A study of Homo sapiens with 24 samples.

How the data were processed

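RNA was measured in 24 samples of HEK293 cells on Illumina bead arrays, 1 array per sample, with biotin-labelled complementary RNA. The 4 groups of 6 arrays were control cells and cells given MOTS-c at 10 µM, each harvested after 4 h or 72 h, and the groups were taken from the sample labels. Per the labels, the authors read the arrays with GenomeStudio 2011.1. The deposited table holds, for each of 47323 probes and each array, a mean bead intensity that was neither background-subtracted nor scaled between arrays. Beside each intensity the deposited table gives a detection p-value, the p_value of the probe against the negative controls of its array. A further deposited table holds a score per probe and array, which was recomputed as the Z score of the log10 intensity within the array, with a largest difference of 5e-10.

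Intensities were processed in R 4.3.3 with limma 3.58.1. The neqc function estimated the background from the detection p-values, applied quantile normalization with an offset of 16 and gave log2 values. Probes with a detection p under 0.05 on at least 6 of the 24 arrays were kept, which left 23931 probes. Of these, 17873 mapped to 1 gene in the probe annotation and 6058 did not, and the latter were left out of the comparisons between groups. Where a gene had more than 1 kept probe, as 3619 genes did, the probe with the highest mean over all arrays stood for it. This left 13283 genes. Transcripts of mitochondrial DNA were not measured by a kept probe with a gene name. Arrays give no counts, and their number limits the precision.

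A linear model with a mean per group was fitted to all 24 arrays with limma, with 20 residual degrees of freedom and a variance prior worth 6.43 more. The contrasts were MOTS-c minus control at 4 h, MOTS-c minus control at 72 h, the difference between these 2 effects (72 h minus 4 h, the interaction), and 72 h minus 4 h in control cells. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All p-values named adjusted below come from limma for single genes, or from camera for gene lists, with Benjamini-Hochberg adjustment. A log2 fold change is the treated (or later) mean minus the control (or earlier) mean, with its standard error (SE) from the model and n = 6 arrays per group. Where a gene was undetected on all 6 arrays of a group, its fold change is given as a lower bound, with no size for the interaction, and a named gene detected on only some of the 6 is given with that count.

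Gene lists, 38 of pathways and 7 of cell type markers, were fixed with the comparisons, filters, tests and the rule for named genes before the data were examined. The 40 lists with at least 5 measured genes were tested with camera at its preset correlation between genes of 0.01. Each list was also tested with camera at an estimated correlation and with fry, whose p-value asks whether the genes of a list move, on balance, one way, with no comparison with other genes. The genes named are the 10 with the largest change each way among called genes whose 6 treated (or later) arrays all lay on the same side of the control mean, the 5 largest each way in the interaction, the 4 members with the smallest p of each called list, and 26 genes of nucleotide, one-carbon, lipid and glucose metabolism whatever their p, of which some are not reported here. A few further genes were named after their values were seen, and the text says so.

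The sources used here do not say how replicate numbers relate between groups. The main fit therefore used no pairing. No shared deviation of same-numbered arrays was seen. The deviations of same-numbered treated and control arrays from their group means correlated between -0.23 and 0.093 at 4 h and between -0.15 and 0.16 at 72 h, and a same-numbered partner was the best match for 0 of 6 numbers at either time. Nothing in the sources used here says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The alternatives covered background correction, normalization, detection filters, the choice of probes, the arrays in the fit, array weights, the variance prior, a replicate block, the thresholds, the set test, and leaving out each array in turn. The model was tested on simulated data with the observed spread, in which log2 changes of 0.3, 0.6 and 1 were added to sets of genes. At 4 h, 47.8%, 92.5% and 100% of these genes were called in the right direction. In the interaction, 20.9%, 86.6% and 98.5% were, so many small changes would be missed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.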

Results

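HEK293, a human embryonic kidney cell line, received water or 10 µM MOTS-c, a 16-residue peptide encoded within a mitochondrial ribosomal RNA gene. Cells were harvested after 4 h or 72 h, and each of the 4 groups was measured on 6 bead arrays. The mean probe intensity per array was 516.5 ± 32.9 (SD, n = 6) in 4 h controls, 520.1 ± 72.7 in 4 h treated cells, 458.8 ± 74.5 in 72 h controls and 483 ± 70.7 in 72 h treated cells. A mean of 21362 probes was detected in 4 h controls, 21421 in 4 h treated cells, 22629 in 72 h controls and 22440 in 72 h treated cells, with single arrays between 20719 and 23405. The first principal component of the normalized levels held 54% of the variance, with group means of -21.8 in 4 h controls, -18.3 in 4 h treated cells, 33.7 in 72 h controls and 6.4 in 72 h treated cells. The second held 12.8% and set the 72 h treated cells apart from the other groups. Its group means were 5.1 in 4 h controls, 4.5 in 4 h treated cells, 8 in 72 h controls and -17.5 in 72 h treated cells.

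The comparison at 4 h asks which transcripts respond soon after the peptide is added. FANCI, a component of the DNA crosslink repair pathway, was the 1 gene called of 13283, with a log2 fold change of -0.39 (SE 0.065, n = 6, limma adjusted p = 0.0329) and lower levels on 6 of 6 treated arrays. At an unadjusted p under 0.05 there were 1567 genes, where 664 would arise by chance among independent genes. Under median scaling there were 711. Of the 23 measured genes of the metabolic panel, 0 were called at 4 h. The panel's smallest p-values belonged to MTR, the methionine synthase, at -0.36 (SE 0.095, limma adjusted p = 0.196), and to PRKAA2, a catalytic subunit of AMP-activated kinase detected on 5 of 6 treated arrays, at -0.34 (SE 0.11, limma adjusted p = 0.259).

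Camera called 2 of 40 gene lists at 4 h, and 7 had an unadjusted p under 0.05. In the list of serine synthesis and ATF4 targets, 0 of 24 genes were called over all genes or adjusted over the list alone. Its mean log2 fold change was 0.074, with camera adjusted p = 0.0437, and adjusted p = 0.924 with an estimated correlation. Its members with the smallest p were the stress transcription factor DDIT3 at 0.24 (SE 0.072), the sestrin SESN2 at 0.26 (SE 0.092), the transfer RNA exporter XPOT at 0.27 (SE 0.090) and the transcription factor CEBPB at 0.14 (SE 0.063). In the list of nuclear-encoded oxidative phosphorylation, 0 of 50 genes were called over all genes or adjusted over the list alone, and its mean of 0.044 turned to -0.02 under median scaling. Its camera adjusted p was 0.0437, and adjusted p = 0.924 with an estimated correlation. Members with the smallest p were the ATP synthase subunits ATP5MC1 at 0.27 (SE 0.082) and ATP5F1E at 0.22 (SE 0.083), and the complex I subunits NDUFB7 at 0.23 (SE 0.068) and NDUFB8 at 0.15 (SE 0.053). Fry called 0 lists. The FANCI call ended under median scaling, with array weights, with a replicate block or with the 4 h arrays alone, where 0 genes were called, and without some single arrays. Other settings called more genes, 33 with array brightness as a covariate, 15 without treated replicate 1, 9 without control replicate 5 and 4 where a detection p under 0.01 on all 24 arrays was required. The calls of both lists ended with Z scores, median scaling, a replicate block or the 4 h arrays alone.

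The comparison at 72 h asks what the cells express after prolonged exposure. Inflammatory mediators were far lower in treated cells. The chemokine CCL20 fell by 2.87 on the log2 scale, a 7.33-fold difference (SE 0.082, n = 6, limma adjusted p = 1.36e-19), and the chemokine CXCL1 fell by 2.77 (SE 0.12). CXCL2, detected on 5 of 6 treated arrays, fell by 2.60 (SE 0.090), CXCL8 by a log2 fold change of -1.97 (SE 0.13), and the cytokine TNF, detected on 1 of 6 treated arrays, fell from a mean log2 level of 7.22 to 5.14, near background. Of 13283 genes, 5984 were called (45.1%), 2936 higher and 3048 lower. Median scaling called 2952 higher and 1737 lower. Among the 5984, 129 differed at least 2-fold, 26 higher and 103 lower. Changes at 72 h went with gene length, longer genes having higher values (Spearman 0.235 over 13272 genes), where at 4 h shorter genes had them (Spearman -0.166).

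Among the other genes with the largest decreases were the transcription factor SOX3 at -2.49 (SE 0.084) and the keratin-associated proteins KRTAP19-1 at -3.15 (SE 0.11) and KRTAP19-6 at -2.82 (SE 0.14), whose gene family holds near-identical copies, so the transcript behind each probe is uncertain. The cytochrome P450 gene CYP2F1 was undetected on all 6 treated arrays and at least 3.76-fold lower. DENND1A was at -2.50 (SE 0.10), but of its 3 probes only 2 had that sign, and they ran from -2.5 to 0.2. The largest increases included ATP6V1C1, a subunit of the vacuolar proton pump, at 1.54 (SE 0.15), but its other probe gave 0.35. It was detected on 3 of 6 control arrays. SLC46A3, a lysosomal transporter, rose by 1.14 (SE 0.068) and the lipid transfer protein gene VPS13A by 1.11 (SE 0.12; 0.19 to 1.11 over its 4 probes). VPS50, of an endosomal recycling complex, rose by 1.10 (SE 0.14; 0.30 at its other probe). ZFC3H1 rose by 1.23 (SE 0.083), LGALSL by 1.17 (SE 0.095) and TYMSOS, an antisense transcript at the thymidylate synthase gene, by 1.11 (SE 0.073). The small nucleolar RNA genes SNORD17 at 1.36 (SE 0.086), SNORA12, detected on 5 of 6 control arrays, at 1.35 (SE 0.26) and SNORD96A at 1.18 (SE 0.069) were also called higher, though such genes lie in host transcripts that a probe can also bind.

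**Figure D1:**
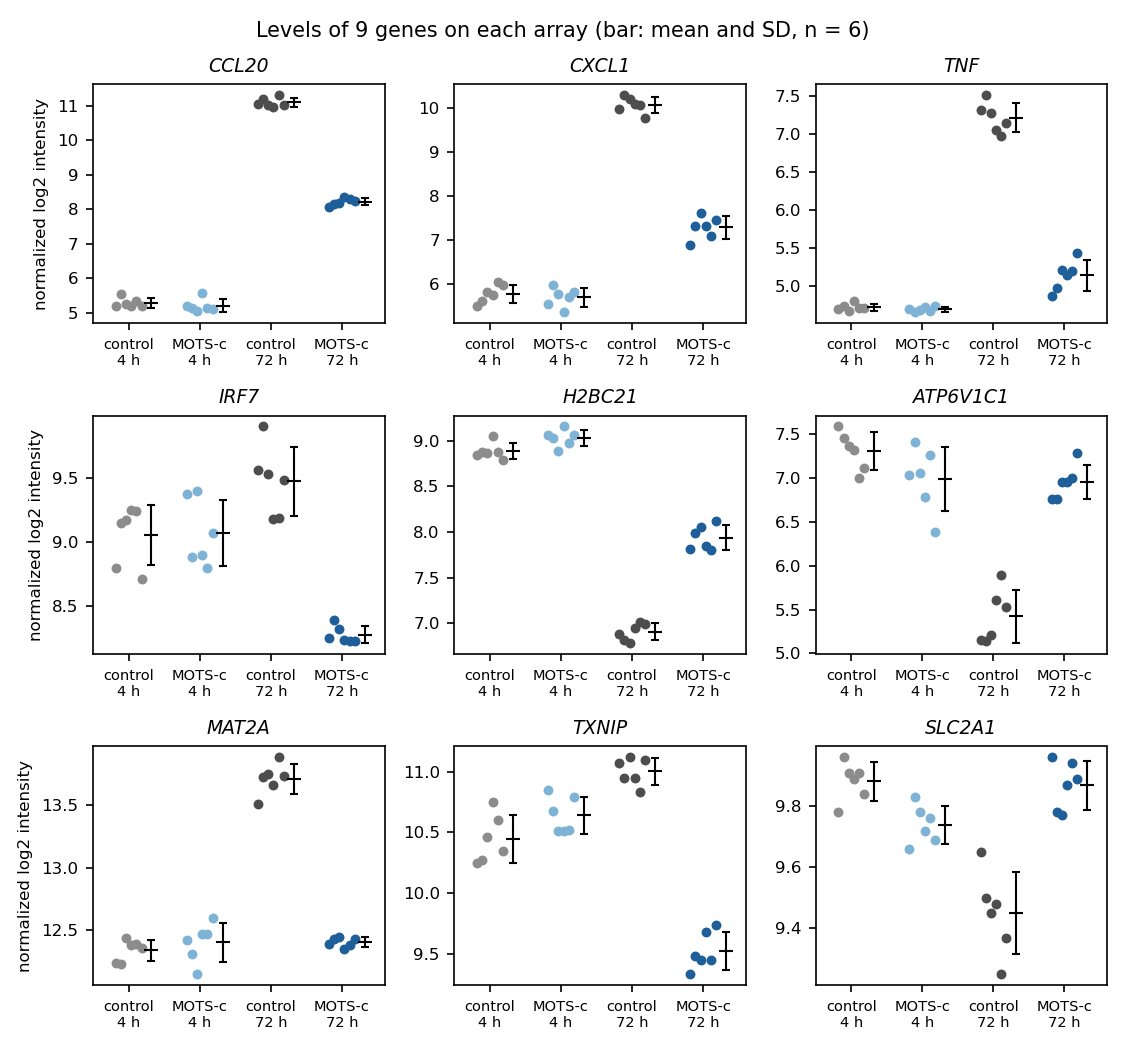
Normalized log2 intensity of 9 genes on each of the 24 arrays, by group, with the mean and SD of n = 6 as bars. CCL20 lay between 10.98 and 11.31 in 72 h controls and between 8.08 and 8.37 in 72 h treated cells.

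Camera called 12 of 40 lists at 72 h, 6 higher and 6 lower, and 3 of the 12 held with an estimated correlation. Of 14 measured NF-kB and inflammatory genes, 12 fell, 1 rose and 1 was not called, with the same counts adjusted over the list alone. The list's mean log2 fold change was -1.18 (camera adjusted p = 3.01e-09), and CCL20, CXCL2, TNF and CXCL1 led it. Of 19 immediate early genes, which growth factors and stress induce, 14 fell and 1 rose, or 15 and 1 adjusted over the list alone, with a mean of -0.47 (camera adjusted p = 2.7e-07). The transcription factor MYC was at -0.97 (SE 0.060), IER3 at -1.06 (SE 0.092), the matricellular protein gene CCN2 at -0.69 (SE 0.071) and the RNA-binding protein gene ZFP36 at -0.60 (SE 0.061). Of 18 ribosome biogenesis genes, 10 fell and 1 rose, or 11 and 1 adjusted over the list alone, with a mean of -0.29 (camera adjusted p = 0.00196). POLR1B, a subunit of RNA polymerase I, was at -0.97 (SE 0.082), and the ribosome assembly factors NOP2 at -0.76 (SE 0.052), RRS1 at -0.66 (SE 0.067) and RRP12 at -0.61 (SE 0.064).

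The other 3 lists called lower were lost with an estimated correlation. Of 23 interferon-stimulated genes, 12 fell, 2 rose and 9 were not called, or 14 and 2 adjusted over the list alone. The mean was -0.26 (camera adjusted p = 0.029; adjusted p = 0.486 with an estimated correlation). The interferon regulatory factor IRF7 was at -1.20 (SE 0.12), the antiviral GTPase gene MX1 at -0.67 (SE 0.11), the ubiquitin-like modifier ISG15 at -0.64 (SE 0.13) and IFIT3 at -0.57 (SE 0.086). Of 24 serine synthesis and ATF4 target genes, 10 fell, 2 rose and 12 were not called, with the same counts adjusted over the list alone. The mean was -0.21 (camera adjusted p = 0.029; adjusted p = 0.486 with an estimated correlation). The members named by the rule were not enzymes of serine synthesis. They were the glutathione-degrading CHAC1 at -0.89 (SE 0.11), DDIT3 at -0.78 (SE 0.072), and the amino acid transporter subunits SLC3A2 at -0.76 (SE 0.081) and SLC7A5 at -0.70 (SE 0.088). Of 9 neuronal and neuroendocrine markers, which HEK293 expresses, 6 fell and 2 rose, with the same counts adjusted over the list alone. The mean was -0.34 (camera adjusted p = 0.0299; adjusted p = 0.126 with an estimated correlation), with the neurofilament genes NEFM at -1.01 (SE 0.060) and NEFH at -0.74 (SE 0.068).

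Histone genes were higher as a list: 10 of 13 rose and 0 fell, with the same counts adjusted over the list alone, at a mean of 0.41 (camera adjusted p = 2.48e-04; adjusted p = 0.207 with an estimated correlation). H2BC21 rose by 1.03 (SE 0.066), H2BC11 by 0.80 (SE 0.097) and H2AC18 by 0.63 (SE 0.092), and near-identical copies leave the gene behind some histone probes uncertain. Of 22 autophagy and lysosome genes, 10 rose and 2 fell, with the same counts adjusted over the list alone, at a mean of 0.20 (camera adjusted p = 0.0158; adjusted p = 0.314 with an estimated correlation). The proton pump subunit ATP6V1H rose 2.01-fold (a log2 change of 0.49 at its other probe), and the autophagy genes WIPI1 and ATG3 rose by 0.74 (SE 0.082) and 0.57 (SE 0.060; 0.23 at the other probe of ATG3) on the log2 scale, whereas the sialidase NEU1 fell by 0.58 (SE 0.085).

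Of 50 nuclear-encoded oxidative phosphorylation genes, 20 rose and 2 fell, with the same counts adjusted over the list alone, at a mean of 0.14 (camera adjusted p = 0.00449; adjusted p = 0.314 with an estimated correlation). The complex I subunits NDUFA6 at 0.66 (SE 0.061) and NDUFA9 at 0.41 (SE 0.072) and the ATP synthase subunit ATP5F1C at 0.38 (SE 0.073) were among them. Of 20 fatty acid oxidation genes, 8 rose and 0 fell, also adjusted over the list alone, at a mean of 0.17 (camera adjusted p = 0.0299; adjusted p = 0.217 with an estimated correlation). ETFDH and ETFA, which carry electrons from this pathway, rose by 0.60 (SE 0.085) and 0.47 (SE 0.063), and the thiolase ACAA2 rose by 0.54 (SE 0.068). Of 19 genes of glycolysis and lactate export, 8 rose and 0 fell, also adjusted over the list alone, at a mean of 0.14 (camera adjusted p = 0.0299; adjusted p = 0.456 with an estimated correlation). The glucose transporter SLC2A1 rose by 0.42 (SE 0.061), PGK1 by 0.37 (SE 0.083), PGAM1 by 0.32 (SE 0.082) and HK1 by 0.24 (SE 0.052; 0.10 at its other probe). Of 20 hypoxia response genes, 10 rose and 1 fell, with the same counts adjusted over the list alone, at a mean of 0.20 (camera adjusted p = 0.029; adjusted p = 0.314 with an estimated correlation). LOX rose by 0.79 (SE 0.15), the mitophagy receptor BNIP3L by 0.61 (SE 0.12), AK4 by 0.52 (SE 0.065; 0.08 to 0.52 over its 5 probes) and the peptide hormone gene ADM by 0.49 (SE 0.059).

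**Figure D2:**
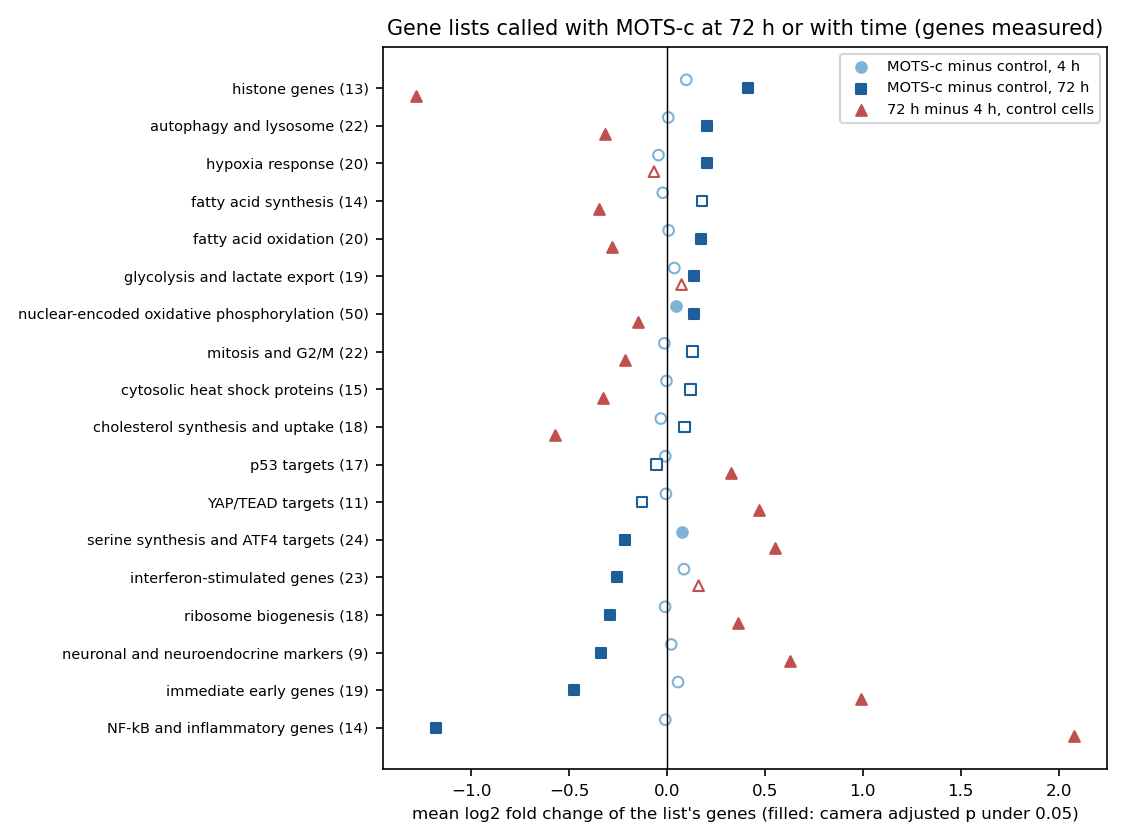
Mean log2 fold change of the measured genes of each list called at 72 h or with time, with the number of measured genes in brackets; circles are MOTS-c at 4 h, squares MOTS-c at 72 h and triangles 72 h minus 4 h in controls, filled where the camera adjusted p was under 0.05. The NF-kB and inflammatory genes had means of -1.18 with MOTS-c at 72 h and 2.08 with time.

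In the metabolic panel, 9 of the 23 measured genes were called at 72 h, 4 higher and 5 lower. TXNIP, an inhibitor of thioredoxin and of glucose uptake, fell by 1.48 (SE 0.089, n = 6, limma adjusted p = 7.97e-13), and MAT2A, which makes S-adenosylmethionine, fell by 1.30 (SE 0.068, limma adjusted p = 4.2e-14). The purine synthesis enzymes PAICS and ATIC rose by 0.24 (SE 0.060; 0.24 to 0.73 over the 3 probes of PAICS) and 0.20 (SE 0.069), whereas PFAS of the same pathway fell by 0.22 (SE 0.056). AHCY, which hydrolyses S-adenosylhomocysteine, fell by 0.18 (SE 0.061). The acetyl-CoA carboxylase genes went apart, ACACB at -0.29 (SE 0.059) and ACACA at 0.15 (SE 0.061, limma adjusted p = 0.0478). The catalytic AMP-activated kinase subunits PRKAA1 at 0.088 (SE 0.081) and PRKAA2, detected on 3 of 6 arrays in each 72 h group and so near background, at 0.038 (SE 0.11) were not called, nor was the coactivator PPARGC1A at 0.21 (SE 0.093). PPARGC1A was called with array weights (limma adjusted p = 0.0453), with array brightness as a covariate (limma adjusted p = 0.0305) and without 72 h control replicate 4 or 5. The glucose transporter SLC2A4 was detected on 1 array and was not tested. Under median scaling the AHCY, PFAS and ACACB calls ended, and the ATIC call ended with the deposited scores or without 72 h control replicate 1. The ACACA call ended with all probes separately, the mean of probes, array weights, a replicate block or the 72 h arrays alone. It also ended in most of the fits that left out a single array.

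Of 12 de novo purine synthesis genes, 4 rose and 1 fell, also adjusted over the list alone, and the list was not called (mean 0.086, camera adjusted p = 0.367). Of 14 folate one-carbon genes, 2 rose and 5 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.904, with a median of 0.053 and a mean of -0.038). Of 10 AMP-activated kinase subunits and upstream kinases, 3 rose and 1 fell, also adjusted over the list alone, and the list was not called (mean 0.046, camera adjusted p = 0.676). Among marker lists of other cell types, 0 of 5 leukocyte markers rose and 1 fell (mean -0.24, camera adjusted p = 0.367), and 0 of 5 keratinocyte and carcinoma markers rose and 1 fell (mean 0.009, camera adjusted p = 0.963). Marker lists with under 5 measured genes were not tested as lists. Of these, 2 of 2 endothelial markers fell (mean -0.62), 1 of 4 fibroblast markers fell (mean -0.20), 1 of 2 kidney tubule markers rose (mean 0.18) and 0 of 2 hepatocyte markers were called. Fry called 29 of the 40 lists at 72 h. Where a detection p under 0.01 on all 24 arrays was required, which removes genes silent at 4 h, 5 lists were called and the inflammatory list was not (mean -0.58, camera adjusted p = 0.0589). The oxidative phosphorylation and glycolysis lists were not called with Z scores, and the ATF4 list was not called under median scaling.

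**Figure D3:**
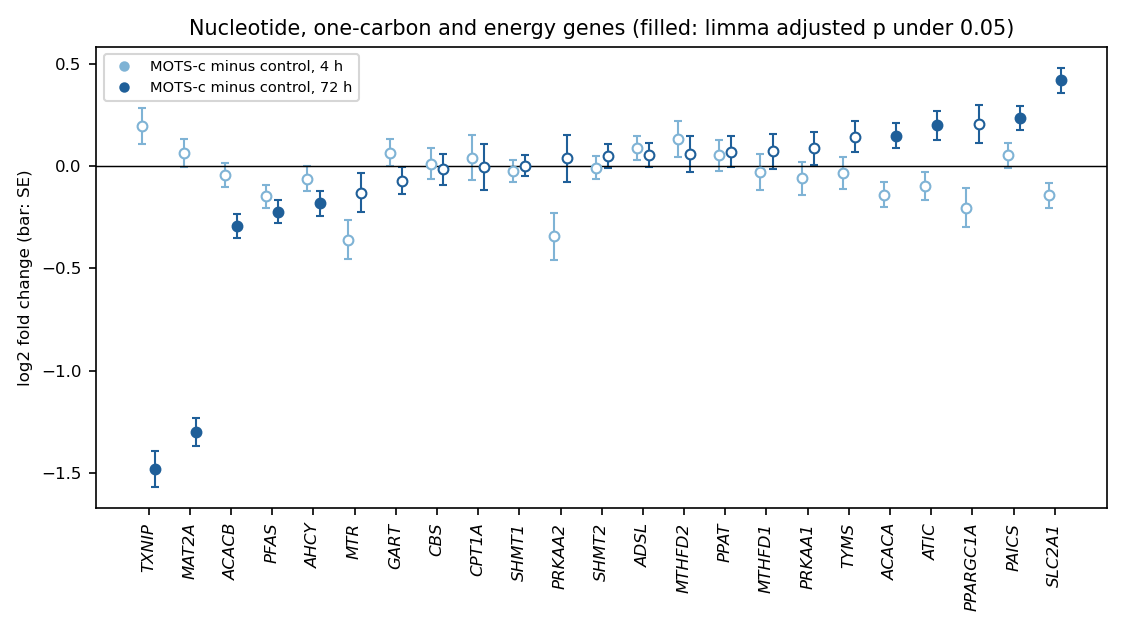
Log2 fold change with MOTS-c of the 23 measured panel genes at 4 h (light) and 72 h (dark), with SE bars and n = 6 arrays per group; filled points have a limma adjusted p under 0.05. TXNIP at -1.48 and MAT2A at -1.30 had the lowest values at 72 h.

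Whether the effect of MOTS-c differed between the times was tested with the interaction, and 4522 of 13283 genes were called, 2217 with a higher and 2305 with a lower effect at 72 h. Median scaling called 1874 and 1144. The effect on CCL20 was lower at 72 h than at 4 h by a log2 difference of -2.79 (SE 0.12, n = 6 arrays in each of 4 groups, limma adjusted p = 2.05e-15) and that on CXCL1, detected on 5 of 6 treated arrays at 4 h, by -2.68 (SE 0.16). CCL20 was detected on 1 of 6 arrays in each 4 h group, so its early effect was measured near background. CXCL2, also called, was undetected on all 12 arrays at 4 h, so no size is given. KRTAP19-1 at -3.27 (SE 0.16) and KRTAP19-6 at -2.84 (SE 0.20) had the other largest negative differences. The largest positive differences were those of ATP6V1C1 at 1.86 (SE 0.21; 0.47 at its other probe), BICD1, a dynein adaptor, at 1.30 (SE 0.22) with 2 of 3 probes of that sign, VPS13A at 1.30 (SE 0.17; 0.30 to 1.30 over its 4 probes), AMER2 at 1.29 (SE 0.12) and SNORD17 at 1.23 (SE 0.12). Among 72 h controls, BICD1 was detected on 3 of 6 arrays and AMER2 on 4 of 6.

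Camera called 9 lists in the interaction, 6 with a lower and 3 with a higher effect at 72 h, and 2 held with an estimated correlation. These were the NF-kB and inflammatory genes, with 10 of 14 lower and 1 higher (11 and 1 adjusted over the list alone; mean -1.17, camera adjusted p = 3.82e-09), and the immediate early genes, with 14 of 19 lower and 1 higher (15 and 1 adjusted over the list alone; mean -0.53, camera adjusted p = 5.13e-08). TNF was called too but was undetected on all 12 arrays at 4 h. IER3 differed by -1.18 (SE 0.13), MYC by -0.94 (SE 0.085) and the phosphatase gene DUSP1 by -0.70 (SE 0.088). Of 24 serine synthesis and ATF4 target genes, 10 were lower and 1 higher, also adjusted over the list alone (mean -0.29, camera adjusted p = 0.00628; adjusted p = 0.415 with an estimated correlation), with CHAC1, detected on 3 of 6 controls at 4 h, at -1.06 (SE 0.15) and DDIT3 at -1.02 (SE 0.10). Of 18 ribosome biogenesis genes, 8 were lower and 0 higher, also adjusted over the list alone (mean -0.28, camera adjusted p = 0.00628; adjusted p = 0.083 with an estimated correlation), with POLR1B at -1.09 (SE 0.12). Of 23 interferon-stimulated genes, 10 were lower and 1 higher (11 and 1 adjusted over the list alone; mean -0.34, camera adjusted p = 0.00881; adjusted p = 0.441 with an estimated correlation), with IRF7 at -1.21 (SE 0.17) and IRF9 at -0.77 (SE 0.17).

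Of 9 neuronal markers, 4 had a lower and 0 a higher effect at 72 h (5 and 1 adjusted over the list alone; mean -0.36, camera adjusted p = 0.0262; adjusted p = 0.0881 with an estimated correlation), with NEFM at -1.16 (SE 0.084). Of 13 histone genes, 6 had a higher and 0 a lower effect, also adjusted over the list alone (mean 0.31, camera adjusted p = 0.00881; adjusted p = 0.415 with an estimated correlation), with H2BC21 at 0.89 (SE 0.093). Of 20 hypoxia response genes, 9 had a higher and 1 a lower effect, also adjusted over the list alone (mean 0.25, camera adjusted p = 0.0262; adjusted p = 0.384 with an estimated correlation), with LOX at 1.06 (SE 0.21) and ANKRD37, detected on 5 of 6 control and 1 of 6 treated arrays at 4 h, at 1.06 (SE 0.22). Of 22 autophagy and lysosome genes, 7 had a higher and 1 a lower effect, also adjusted over the list alone (mean 0.20, camera adjusted p = 0.0301; adjusted p = 0.415 with an estimated correlation), with ATP6V1H at 1.05 (SE 0.12, and 0.45 at its other probe). Across the 13283 genes, which are not independent replicates, the log2 fold changes with MOTS-c at 4 h and 72 h correlated at Pearson -0.11 and Spearman -0.12, and 45.9% had the same sign. At both times 0 genes were called, where 0.229 would be expected by chance. Fry called 25 lists in the interaction, camera called 15 under median scaling and 5 with the stricter detection filter. With that filter the inflammatory list was not called in the interaction (mean -0.51, camera adjusted p = 0.17), nor were the hypoxia, autophagy and neuronal lists.

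**Figure D4:**
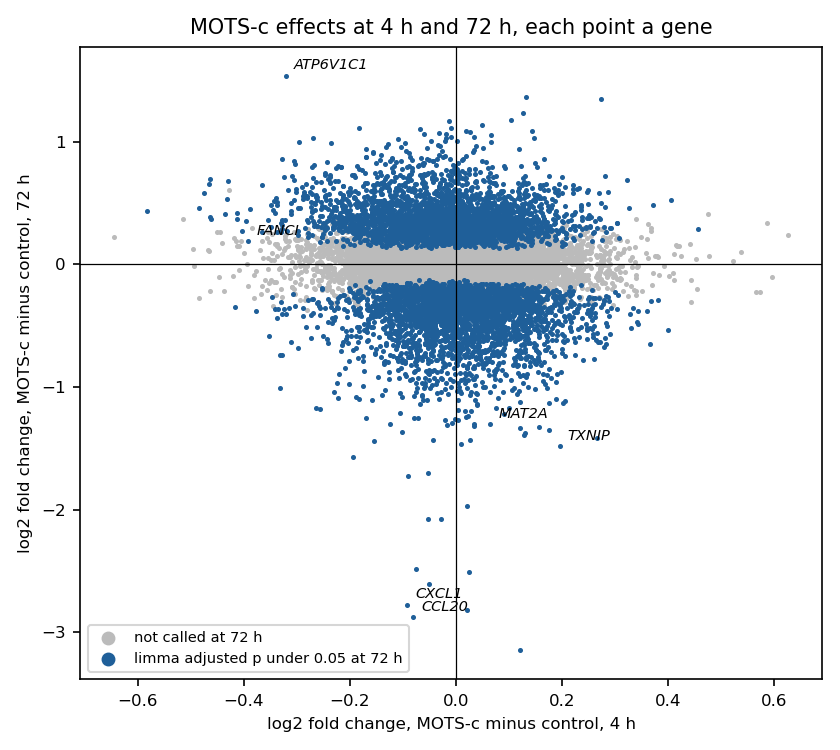
Log2 fold change with MOTS-c at 4 h (horizontal) and 72 h (vertical) of each of 13283 genes, in blue where the limma adjusted p at 72 h was under 0.05. CCL20 lies at -2.87 on the 72 h axis, and the Pearson correlation across genes was -0.11.

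The comparison of control cells between 4 h and 72 h gives the background of time in culture without the peptide. The sources used here name no chip or batch, so a batch difference between these groups cannot be told apart from time. CCL20, detected on 1 of 6 early arrays, rose from a mean log2 level of 5.29, near background, to 11.1 (n = 6, limma adjusted p = 1.36e-27). CXCL8 rose by 4.80 on the log2 scale (SE 0.13), CXCL1 by 4.27 (SE 0.12) and the cytokine IL32 by 3.43 (SE 0.11). CXCL2 was undetected on all 6 early arrays and at least 6.53-fold higher at 72 h, and the pseudogene NAPSB was likewise at least 4.28-fold higher. LAD1 rose by 2.85 (SE 0.080), SNORD13 by 2.71 (SE 0.27), KRTAP19-1 by 3.32 (SE 0.11) and KRTAP19-6 by 3.07 (SE 0.14). Decreases were led by the histone genes H2AC6 at -2.00 (SE 0.089), H2BC21 at -1.98 (SE 0.066), H1-2 at -1.85 (SE 0.084) and H2BC5 at -1.82 (SE 0.084), and by ATP6V1C1 at -1.89 (SE 0.15; -0.55 at its other probe), detected on 3 of 6 late arrays. MFSD1 was at -1.74 (SE 0.082), the nutrient-sensing GTPase gene RRAGB at -1.72 (SE 0.071), SOX2 at -1.71 (SE 0.13; -0.82 at its other probe), VPS50 at -1.71 (SE 0.14; -0.52 at its other probe) and PCDH7 at -1.73 (SE 0.075), the last with 2 probes of opposite sign. In all, 8320 genes were called, 4237 higher and 4083 lower, and 591 differed at least 2-fold.

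Camera called 15 lists with time, 7 higher and 8 lower, and 8 held with an estimated correlation. Of 14 NF-kB and inflammatory genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone; mean 2.08, camera adjusted p = 1.29e-08). Of 19 immediate early genes, 17 rose and 1 fell, also adjusted over the list alone (mean 0.99, camera adjusted p = 9.95e-10), with FOSB at 1.75 (SE 0.074), ATF3 at 1.61 (SE 0.055) and EGR1 at 1.56 (SE 0.076). Of 9 neuronal markers, 7 rose and 1 fell, also adjusted over the list alone (mean 0.63, camera adjusted p = 0.00581), with NEFM at 1.81 (SE 0.060), and of 18 ribosome biogenesis genes, 11 rose and 2 fell, also adjusted over the list alone (mean 0.36, camera adjusted p = 0.00617), with RRP12 at 1.63 (SE 0.064). Of 13 histone genes, 12 fell and 0 rose, also adjusted over the list alone (mean -1.28, camera adjusted p = 2.7e-09). Of 18 genes of cholesterol synthesis and uptake, 13 fell and 0 rose, also adjusted over the list alone (mean -0.57, camera adjusted p = 2.02e-04), with the enzyme genes MSMO1 at -1.62 (SE 0.072) with 2 of 3 probes of that sign, IDI1 at -1.37 (SE 0.10) and HMGCS1 at -1.34 (SE 0.090). Fatty acid genes were lower as well, with 13 of 20 oxidation genes down and 1 up (mean -0.28, camera adjusted p = 0.00389) and 9 of 14 synthesis genes down and 3 up (mean -0.35, camera adjusted p = 0.0128), both with the same counts adjusted over the list alone. The desaturase FADS2, detected on 5 of 6 late arrays, was at -1.21 (SE 0.12). Among marker lists too short to test, 2 of 2 endothelial markers (mean 0.65) and 3 of 4 fibroblast markers (mean 0.34) rose and 1 of 2 kidney tubule markers fell (mean -0.41).

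The other 7 lists were lost with an estimated correlation. Of 24 serine synthesis and ATF4 target genes, 16 rose and 2 fell, also adjusted over the list alone (mean 0.55, camera adjusted p = 2.02e-04; adjusted p = 0.17 with an estimated correlation), with DDIT3 at 1.96 (SE 0.072) and the kinase-like TRIB3 at 1.41 (SE 0.082). Of 17 p53 targets, 10 rose and 1 fell, also adjusted over the list alone (mean 0.33, camera adjusted p = 0.0239; adjusted p = 0.137 with an estimated correlation), with GADD45A at 1.06 (SE 0.080). Of 11 YAP/TEAD targets, 5 rose and 1 fell, also adjusted over the list alone (mean 0.47, camera adjusted p = 0.0295; adjusted p = 0.0661 with an estimated correlation), with ANKRD1 at 2.03 (SE 0.11). Of 15 cytosolic heat shock genes, 9 fell and 1 rose, also adjusted over the list alone (mean -0.33, camera adjusted p = 0.00669; adjusted p = 0.0846 with an estimated correlation), with HSPH1 at -0.73 (SE 0.074). Of 22 autophagy and lysosome genes, 12 fell and 4 rose, also adjusted over the list alone (mean -0.32, camera adjusted p = 0.00867; adjusted p = 0.217 with an estimated correlation), with LAMP1 at -0.98 (SE 0.073). Of 22 mitosis and G2/M genes, 13 fell and 3 rose (14 and 3 adjusted over the list alone; mean -0.21, camera adjusted p = 0.0209; adjusted p = 0.217 with an estimated correlation), with the checkpoint kinase BUB1 at -0.82 (SE 0.090) and the mitotic kinase AURKB at 0.70 (SE 0.072). Of 50 oxidative phosphorylation genes, 20 fell and 4 rose (19 and 4 adjusted over the list alone; mean -0.15, camera adjusted p = 0.0295; adjusted p = 0.376 with an estimated correlation), with ATP5MC3 at -0.94 (SE 0.10).

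Most MOTS-c changes at 72 h ran against the change with time in control cells. Of the 5984 genes called at 72 h, 75.9% were called in the opposite direction with time, among them CCL20, CXCL1, MAT2A and H2BC21. Both contrasts use the same 72 h controls. With these split 3 and 3 so that the contrasts shared no array, the share had a mean of 71.7% (61.8% to 78.1% over 20 splits). Fry called 31 lists with time. Under the stricter detection filter the inflammatory list was not called with time (mean 0.91, camera adjusted p = 0.111).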

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

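The tests of split controls, array brightness, a steady course in time, leukocyte markers, other genes of the same lengths and the permutation of the 12 early arrays were chosen after the results were seen, whereas the counts of other splits of the arrays and the test of the shortest other genes were set out before their results. Among 48 groups of 6 arrays tested for a single far value (9 plotted genes and further measures per array), 2 held one, about what chance gives at 1 in 20. CCL20 on 4 h treated replicate 4 was at a log2 level of 5.58, where the other arrays of the group lay between 5.05 and 5.2. H2BC21 on 4 h control replicate 4 was at 9.05, where the others lay between 8.79 and 8.88.

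The effect of MOTS-c differed between 72 h and 4 h, by the interaction test, for 4522 genes. Among the genes with the largest differences, ATP6V1C1 was at 1.86, BICD1 at 1.30, VPS13A at 1.30, AMER2 at 1.29 and SNORD17 at 1.23. On the negative side, KRTAP19-1 was at -3.27, KRTAP19-6 at -2.84, CCL20 at -2.79, detected on 1 of 6 arrays in each 4 h group, and CXCL1 at -2.68. CXCL2 was also called (limma adjusted p = 6.09e-14), with no size given because it was undetected on all 12 arrays at 4 h. Of the 138 other named genes, 104 had a called difference, beside 34% of all 13283 genes. Many of the 138 were named for their changes on these same arrays, so a high share was built in. Of the gene lists with a called difference, means were -1.17 for NF-kB and inflammatory genes, -0.53 for immediate early genes, -0.36 for neuronal markers, -0.34 for interferon-stimulated genes, -0.29 for serine synthesis and ATF4 targets, -0.28 for ribosome biogenesis, 0.31 for histone genes, 0.25 for hypoxia response and 0.20 for autophagy and lysosome. Of 6058 detected probes with no single gene in the annotation, which the comparisons did not use, 1480 were called at 72 h by limma, 805 higher and 675 lower. That is 24.4%, beside 42.2% of the probes with 1 gene.

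Other splits of the same arrays into groups of the same sizes were drawn, 100 per comparison with the real one included. At 4 h, 18 of 100 splits gave at least the real 1 gene (highest other 6) and 26 gave at least the real 2 lists (highest other 5), so chance was not excluded for either count. At 72 h, 1 of 100 splits, the real one, reached 5984 genes (highest other 5254) and 1 of 100 reached 12 lists (highest other 11). In the interaction, 1 of 100 reached 4522 genes (highest other 3945) and 2 of 100 reached 9 lists (highest other 13). With time in control cells, 1 of 100 reached 8320 genes (highest other 4559) and 3 of 100 reached 15 lists (highest other 15). For each of these last 6 counts, the share of splits that reached it was under 0.05, which argues against a random assignment of these arrays to groups. Splits of arrays cannot exclude a chance difference between single cultures or batches, since nothing in the sources says that the replicates came from separate cultures.

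MOTS-c changes at 72 h opposed the changes with time in control cells: the log2 fold changes correlated at -0.75 across genes (covariance -0.12), beside -0.497 (covariance -0.00458) in simulations with shared controls and no effect. Higher with time and lower with MOTS-c were 2342 genes, and 2200 were the opposite, where independent lists, which leave out the shared controls, would give 972 and 902. With the 72 h controls split 3 and 3 between the contrasts, the mean correlation was -0.703 (-0.749 to -0.633 over 20 splits, mean covariance -0.115). That argues against noise of single control arrays used in both contrasts as the whole source. A deviation common to all the 72 h controls would stay in both parts, so the splits cannot exclude it. With array brightness removed, the mean correlation was -0.665. The 72 h groups overlapped in brightness, which leaves such a covariate little to remove, so that value decides nothing. A biological hypothesis, that treated cells may stand at an earlier point of the course that controls follow, is argued against, if that course is steady between 4 h and 72 h, for 104 of the 4542 opposing genes, 2.3% and under the 5% first set for excluding it for the pattern as a whole, among them IRF7, TXNIP and SOX3, whose treated 72 h levels lay past the 4 h control level in all 4 normalizations. For the other 4438 genes an earlier point and a separate effect of the peptide cannot be told apart, because no cells were measured between the times, which also leaves a transient course open for the 104, and the gene lists do not settle it, since 5 lists had means outside both control means with the main normalization but 4 with no background correction, 1 with median scaling and 0 with Z scores.

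Small RNA genes (small nucleolar, small Cajal body and spliceosomal RNAs, 110 genes) were higher with MOTS-c at 4 h by a median log2 of 0.16, 94 higher and 16 lower, although 0 were called by limma and 30 had an unadjusted p under 0.05, and at 72 h the median was 0.11, with 26 called higher and 5 lower. Shorter genes had higher values at 4 h (Spearman -0.166 over 13272 genes, and 0.235 at 72 h, where longer genes had them). A gene length trend alone did not give the value of the small RNA genes in other short genes. The 110 shortest other genes, of up to 641 bp, had a median of 0.041 (95% bootstrap interval over genes 0.02 to 0.074). The 66 no longer than the longest small RNA gene (353 bp) had 0.024 (-0.002 to 0.077). The 38 of these at levels like those of the small RNA genes had 0.026 (-0.002 to 0.104), beside 0.162 for 82 small RNA genes. The small RNA class was singled out for its 4 h values, so part of this gap was built in. A length trend joined by chance therefore stays open. Array brightness overlapped between the 4 h groups, with a mean log2 intensity per array of 7.024 to 7.159 in controls and 6.896 to 7.303 in treated cells. With brightness as a covariate the median was 0.151, but groups alike in brightness leave such a covariate little to remove, so that value decides nothing. Chance among the 12 arrays stays open, because the class was singled out for its 4 h values on the same arrays, which the exact permutation p of 0.0108 for the mean level per array does not allow for. On the 72 h arrays the mean level was higher by 0.152 (exact permutation p = 0.00216). Since 45.1% of all genes were called at 72 h, that value does not settle the one at 4 h. The median at 4 h was 0.098 with no background correction, 0.17 with median scaling and 0.078 in SD units with Z scores. A difference in RNA quality or labelling between the groups and a response to the peptide also remain open and may act together, and no value held here separates them.

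Inflammatory genes were high in 72 h control cells and lower with MOTS-c. Leukocytes in the control cultures are argued against, since of 9 leukocyte markers 1 was detected on all 6 arrays of the 72 h controls and called higher than at 4 h (CD14, log2 fold change 0.28, limma adjusted p = 0.00504). CD79A, LYZ and CD68 were also detected on all 6 of those arrays but were not called with time (0.022, 0.18 and -0.09). LYZ was detected on 4 of 6 control arrays at 4 h. MS4A1 was detected on 3 of the 72 h control arrays, and PTPRC, CD3D, CD3E and TYROBP on 0. Array brightness overlapped between the 72 h groups, with a mean log2 intensity per array of 6.746 to 7.18 in controls and 6.716 to 7.026 in treated cells. With brightness as a covariate the list's mean at 72 h was -1.181. Groups alike in brightness leave such a covariate little to remove, so that value decides nothing. A response of the cells themselves, damped by the peptide, stays a hypothesis, and a difference between the 72 h cultures in density or medium, for which no values are given in the sources used here, may contribute as well.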

How the results depend on the processing

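The fit with array brightness as a covariate was chosen after the results were seen, and the other alternatives were planned. Of 232 results for named genes, 221 kept their side of the threshold under every alternative run for single genes, which leaves out the stricter thresholds. The same held for 9 of 38 results for named lists. A change of sign was counted only where the reported fit or the alternative called the result. Genes called in neither may therefore have changed direction and still be among the 221. The correlation between the times stayed between -0.154 and -0.106 under the other settings (jackknife SE 0.096) and between -0.164 and -0.078 when single arrays were left out. The 4 h gene count of 1 became 3 with no background correction, 0 with median scaling, 2 with Z scores or the deposited scores, 4 with detection p under 0.01 on all 24 arrays, 3 with all probes separately, 0 with only the groups compared, 0 with array weights, 2 with the trended robust prior, 0 with the replicate block, 0 at an adjusted p under 0.01 and 33 with brightness. The 4 h list count of 2 became 0 with Z scores or the deposited scores, 5 with the mean of probes, 0 with only the groups compared, 1 with array weights, 0 with the block, 0 with brightness, 0 with an estimated correlation and 0 with fry. With the stricter detection filter, which tests 9632 genes, the list count fell from 12 to 5 at 72 h and from 9 to 5 in the interaction. With an estimated correlation 3 lists were called at 72 h (fry 29), 2 in the interaction (fry 25) and 8 with time (fry 31). Median scaling called 15 lists in the interaction and, beside 49.1% and 49% in the reported fit, put 63% of called genes higher at 72 h and 62.1% in the interaction. At an adjusted p under 0.01 the interaction called 2980 genes. DENND1A at 72 h turned from -2.50 to 0.20 with the stricter filter, which leaves another of its probes. With the replicate block, 5799 genes were called at 72 h, 4292 in the interaction and 8220 with time. The cause of these shifts was not tested, apart from the probe of DENND1A. Leaving out single arrays, the 4 h gene count ran from 0 to 15: 15 without treated replicate 1, 9 without control replicate 5, 3 without treated replicate 5, 2 without control replicate 6, 72 h control replicates 4 and 5 or 72 h treated replicate 5, and 0 without control replicates 1, 2 and 4, treated replicates 3 and 4, 72 h control replicates 3 and 6 or 72 h treated replicates 1, 3 and 4; without treated replicate 6 the 1 gene called was not FANCI. The 4 h list count ran from 0 (without treated replicate 1) to 4 (without treated replicate 4), with 1 without control replicates 1, 2, 3, 5 and 6 or treated replicates 2 and 3. At 72 h, 5477 to 6382 genes and 11 to 13 lists were called, in the interaction 4078 to 5097 genes and 8 to 11 lists, and with time 7967 to 8430 genes and 15 to 15 lists. A chip block was not run, since the sources used here name no chips, and with only the groups compared the interaction and the correlation use the same arrays as before. The trended prior does not enter the correlation. The deposited scores are Z scores, so no log was taken. Signal over background limits genes near the detection limit, such as the inflammatory genes at 4 h.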

Other observations

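Mitochondrial ribosomal protein genes, which serve translation inside the organelle, went both ways with MOTS-c at 72 h: of 30 measured, 15 fell and 8 rose (15 and 9 adjusted over the list alone), with a mean log2 fold change of -0.11 that camera did not call (adjusted p = 0.261). Of 14 genes of mitochondrial biogenesis and genome maintenance, 6 fell and 2 rose (6 and 4 adjusted over the list alone), with a mean of -0.11 (camera adjusted p = 0.451). Of 14 fatty acid synthesis genes, 8 rose and 2 fell, also adjusted over the list alone, with a mean of 0.18 (camera adjusted p = 0.0692). Of 22 mitosis and G2/M genes, 8 rose and 2 fell, also adjusted over the list alone, with a mean of 0.13 (camera adjusted p = 0.0989).

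Cytosolic ribosomal protein genes stood near 0 at 72 h: 3 of 43 rose and 1 fell (1 and 1 adjusted over the list alone), with a mean of 0.008 and a median of -0.007 (camera adjusted p = 0.919). Of 20 DNA replication and G1/S genes, 3 rose and 3 fell (3 and 2 adjusted over the list alone), with a mean of -0.004, a median of 0 and a camera test in the positive direction (adjusted p = 0.904). Of 9 housekeeping reference genes, 4 rose and 1 fell, also adjusted over the list alone, with a mean of 0.10 (camera adjusted p = 0.367). Among the 3619 genes with several kept probes, the probes differed in sign for 51.6% at 4 h, 28.4% at 72 h and 31.7% with time. Probes of the same gene were called in opposite directions for 0 genes at 4 h, 78 at 72 h, 50 in the interaction and 259 with time.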
